A study of Mus musculus with 6 samples.

How the data were processed

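Bulk RNA-seq of 6 libraries was compared, 3 from the mouse endothelial line bEnd.3 and 3 from the mouse endothelial line UV2. Per the labels' protocols, cells on 10-cm dishes were washed after confluency and kept in serum-free medium for 3 days, detached with trypsin-EDTA, and their RNA was purified with an RNeasy Micro Kit and made into libraries with a TruSeq Stranded mRNA kit. Samples were grouped by the cell line named in the labels, and replicate numbers came from the sample titles.

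The submitters' processing notes name Trim Galore, STAR and RSEM and the genome build mm10. Tool versions, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited a table of expected counts per gene symbol, not normalized, with 24411 genes and a column for each library. Expected counts share reads that fit several genes among them, so members of families of close copies (H2, Schlafen, Ifit and Oas genes) and genes that overlap are uncertain. Between 8.23% and 8.73% of genes per library had values that were not whole. The reference is a C57BL/6 genome, from which BALB/c reads differ at strain variants, and this can lower their mapping.

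Total expected counts were 21306441 to 28748128 per library, with 14614 to 15205 genes detected, and the 10 most abundant genes took 5.35% to 5.71% of the counts in bEnd.3 and 3.96% to 4.14% in UV2. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 12720 of 24411 genes, and 7128 genes had a count of 0 in every library. TMM factors were 1.016 to 1.027 in bEnd.3 and 0.969 to 0.995 in UV2. The comparison was fitted with edgeR's quasi-likelihood test with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with calls at an adjusted p under 0.05. Changes beyond 2-fold were tested with edgeR's glmTreat on the same fit. The biological coefficient of variation was 0.124. Levels are CPM from TMM-scaled library totals. A gene with 0 counts in all libraries of a line was set against a floor of 3 counts over the 3 libraries and its fold is a lower bound, and a gene with 1 to 3 counts has a ratio with an exact 95% counting interval.

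Gene lists and markers of other cell types, 26 lists in all, the test, the rule for named genes and the alternatives were fixed before the data were examined. Lists were tested with camera with a preset correlation of 0.01, two-sided and adjusted over the 24 lists with at least 2 tested members. The rule named the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher line and no overlap between lines, leaving out predicted genes named Gm plus digits, Rik clones, pseudogenes and mitochondrial genes. It also named the highest and lowest called member of each list with at least 1 CPM in the higher line (the 2 largest where all went one way), and always Pecam1, Cdh5, Kdr, Cldn5, Vwf, Prox1, Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Other genes named in the text were chosen after their values were seen. A gene that the rule named is not reported here.

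Alternatives were size factors as in DESeq2, total counts, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2, limma-voom, camera with an estimated correlation and fry. Removal of each chromosome's median was added after seeing the data. For it, chromosome 4 was parted at the point that best separated these same fold changes, and each part's own median was removed. Gene positions came from the RefSeq table of GRCm38.p6, the assembly of mm10, to which 99.7% of tested genes were matched by symbol. Chromosome medians used the 9576 genes with edgeR's average log2 CPM (its logCPM value) above 3. That value is not the mean of the libraries' log2 CPM. Replicates were checked for duplicates by a chi-square of their counts, which was 11.7 to 40.2 per degree of freedom, so none was a copy of another.

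The procedure was tested on simulated data, 5 sets with the means and library sizes of these libraries. The same 200 genes, drawn from genes outside the lists with a mean of at least 1 CPM, were changed in each. Tested members of the basement membrane list were raised 2-fold as well. Of the 200 drawn genes, 84.2% of those changed 2-fold and 98.8% of those changed 4-fold were called. The right sign was found for 100% of the drawn genes called. Of the genes called, 8.65% had not been changed, a larger share than the adjusted p of 0.05 allows on average. Of unchanged genes, 0.150% were called. In the real data 67.1% of tested genes were called, far more than were changed in the simulation, so these rates may not carry over. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.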

Results

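The data were 6 bulk RNA-seq libraries from 2 mouse endothelial cell lines, bEnd.3 and UV2, with 3 libraries of each. bEnd.3 is a brain endothelial line immortalised with polyomavirus middle T antigen, and its strain is given as BALB/c. The labels also write UV2 as UV♀2 and give its strain as (BALB/c x C57BL/6)F1. Confluent cells on 10-cm dishes had been kept without serum for 3 days before the RNA was taken. Total expected counts were 21944529, 23923524 and 28748128 in bEnd.3 replicates 1, 2 and 3. They were 23791623, 21306441 and 26769149 in UV2 replicates 1, 2 and 3. Nothing in the labels says that the 3 libraries of a line came from separate cultures, so p-values measure the spread between these libraries only, which may be technical. Sequenced reads are not independent molecules, so counting intervals and floors cover counting error only. Levels below are CPM (counts scaled to a common library total after TMM normalisation), as mean ± SD over n = 3 libraries, and log2 fold changes are UV2 minus bEnd.3 with standard errors (SE). Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

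The design set these 2 endothelial lines against each other under the same serum-free culture, and no purpose was stated for it. The endothelial genes Pecam1, Cdh5 and Kdr were abundant in both lines. UV2 had almost no transcript of the tight-junction gene Cldn5. Its HOXA cluster, von Willebrand factor and major histocompatibility complex (MHC) class I transcripts were above those of bEnd.3. For the class I H2 genes, the line and a loss of BALB/c reads against the reference cannot be told apart. Most genes of a list of p53 targets were lower in UV2, Cdkn1a among them. Of 12720 genes tested, 4306 were higher and 4232 lower in UV2, and 4182 did not pass the test. By more than 2-fold, 1350 genes were higher and 1120 lower. The libraries of the lines did not overlap at 9316 genes, 73.2% of those tested, where chance gives 10%. Coordinates below are those of the mm10 build (GRCm38.p6 RefSeq table). Of the set tests by camera, run over 24 lists with a preset correlation, 8 gene lists and 1 marker list were called (2 marker lists with the replicate number as a block), and with an estimated correlation only the Hox and p53 lists held. Mixed splits of the same 6 libraries gave up to 9 called gene lists and up to 2 marker lists with the preset correlation. Such splits keep a part of the line difference, so these numbers do not measure chance alone.

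Genes with the largest differences had 0 or few counts in 1 of the lines. Pcdh17, a protocadherin (chromosome 14, 84443563 to 84537565), stood at 185 ± 26.3 CPM in bEnd.3 and had 0 counts in UV2, at least 4326-fold lower (adjusted p = 8.71e-07). Mn1, a transcriptional co-regulator (chromosome 5, 111417300 to 111457030), was at least 2701-fold lower in UV2, from 115 ± 20.2 CPM in bEnd.3. Inhbb, the activin beta-B subunit (chromosome 1, 119415463 to 119422248), was at least 2167-fold lower, from 92.5 ± 34.1 CPM. Cdc42ep5, an effector of the GTPase Cdc42 (chromosome 7, 4151260 to 4164831), was at least 1121-fold lower, and Atp9a, a P-type ATPase (chromosome 2, 168634438 to 168742370), was at least 707-fold lower, from 47.9 ± 5.55 CPM and 30.2 ± 2.83 CPM. Slfn5, a Schlafen family gene (chromosome 11, 82951349 to 82964850), had 1059 ± 93.4 CPM in bEnd.3 and 0.195 ± 0.133 CPM in UV2 (log2 fold change -12.44, SE 0.23, adjusted p = 4.14e-08). Without UV2 replicate 2 its log2 fold change was -13.03. In the other direction, Glipr1 (chromosome 10, 111985448 to 112002639), Chrna7, the alpha-7 nicotinic acetylcholine receptor subunit (chromosome 7, 63098692 to 63212526), and Mxra7 (chromosome 11, 116803400 to 116828127) had 0 counts in bEnd.3. Their levels in UV2 were 29.7 ± 4.13 CPM, 28.5 ± 4.76 CPM and 26.5 ± 2.08 CPM, at least 756-fold, at least 726-fold and at least 675-fold higher. Glod5 on the X chromosome (chromosome X, 8004201 to 8018492) had 2 counts in the bEnd.3 libraries together and 186 ± 41.6 CPM in UV2, a ratio of 7109 (95% counting interval 1968 to 58708), with a fitted log2 fold change of 11.91 without bEnd.3 replicate 3. Folds against 0 counts were set against a floor of 3 counts over the 3 libraries of the line, which is 0.0393 CPM in bEnd.3 and 0.0427 CPM in UV2.

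Sex-linked transcripts separated the lines completely. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460373 to 103483233), had 0.175 ± 0.166 CPM in bEnd.3 and 1181 ± 102 CPM in UV2 (log2 fold change 12.71, SE 0.28, adjusted p = 6.13e-08). Its log2 fold change was 13.81 without bEnd.3 replicate 2. The Y-linked Ddx3y (chromosome Y, 1260715 to 1286628) had 148 ± 7.36 CPM in bEnd.3 and 0.05802 ± 0.0512 CPM in UV2 (log2 fold change -11.22, SE 0.22, adjusted p = 4.42e-08). Uty, Kdm5d and Eif2s3y stood at 45.7 ± 1.68 CPM, 48.03 ± 3.12 CPM and 62.7 ± 6.08 CPM in bEnd.3 and held 1, 2 and 3 counts in the UV2 libraries together. The bEnd.3 to UV2 ratios were 3221 (95% counting interval 578 to 127251) for Uty, 1694 (95% counting interval 469 to 13991) for Kdm5d and 1474 (95% counting interval 504 to 7148) for Eif2s3y. Their fitted log2 fold changes moved to -13.13 for Uty without UV2 replicate 1, -13.18 for Kdm5d without UV2 replicate 3 and -11.28 for Eif2s3y without UV2 replicate 2. Tsix overlaps Xist on the opposite strand and the strand setting of the counting was not stated, so the Xist level is uncertain to that extent.

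Among pan-endothelial genes, the adhesion molecules Pecam1 and Cdh5 and the VEGF receptor Kdr were high in both lines and did not pass the test. Pecam1 (chromosome 11, 106654213 to 106715281) had 1951 ± 73.4 CPM in bEnd.3 and 2166 ± 52.1 CPM in UV2 (log2 fold change 0.15, SE 0.07, adjusted p = 0.0927), although it passed in DESeq2 (adjusted p = 0.0434) and with chromosome medians removed (adjusted p = 0.017). Cdh5 had 3958 ± 273 against 4039 ± 149.8 CPM (log2 fold change 0.03, SE 0.08, adjusted p = 0.774), with bEnd.3 first here and after, and Kdr had 1554 ± 240.0 against 1599 ± 301 CPM (log2 fold change 0.04, SE 0.16, adjusted p = 0.837). The signs of Cdh5 and Kdr turned with total counts. Cldn5, the main claudin of endothelial tight junctions (chromosome 16, 18776847 to 18778262), fell from 1052 ± 63.3 CPM in bEnd.3 to 0.262 ± 0.0736 CPM in UV2 (log2 fold change -11.97, SE 0.15, adjusted p = 1.05e-08). Mmrn2, an endothelial matrix protein, fell from 189.8 ± 3.43 CPM to 1.14 ± 0.607 CPM (log2 fold change -7.35, SE 0.24), and Rasip1, a vascular Ras-interacting protein, fell from 492 ± 12.6 CPM to 33.2 ± 3.17 CPM (log2 fold change -3.89, SE 0.09). Vwf, the platelet-binding glycoprotein of Weibel-Palade bodies (chromosome 6, 125552948 to 125686679), rose from 84.6 ± 47.6 CPM to 870.0 ± 74.1 CPM (log2 fold change 3.36, SE 0.46, adjusted p = 0.000366), and the transcription factor Sox7 rose from 50.9 ± 3.38 CPM to 344 ± 29.5 CPM (log2 fold change 2.76, SE 0.09). In this list 7 of 30 tested members were higher in UV2, 15 were lower and 8 did not pass the test. Counts adjusted over the list alone were the same. The list was called lower by camera (adjusted p = 0.000815; adjusted p = 0.415 with an estimated correlation), with a median log2 fold change of -0.29.

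**Figure D1:**
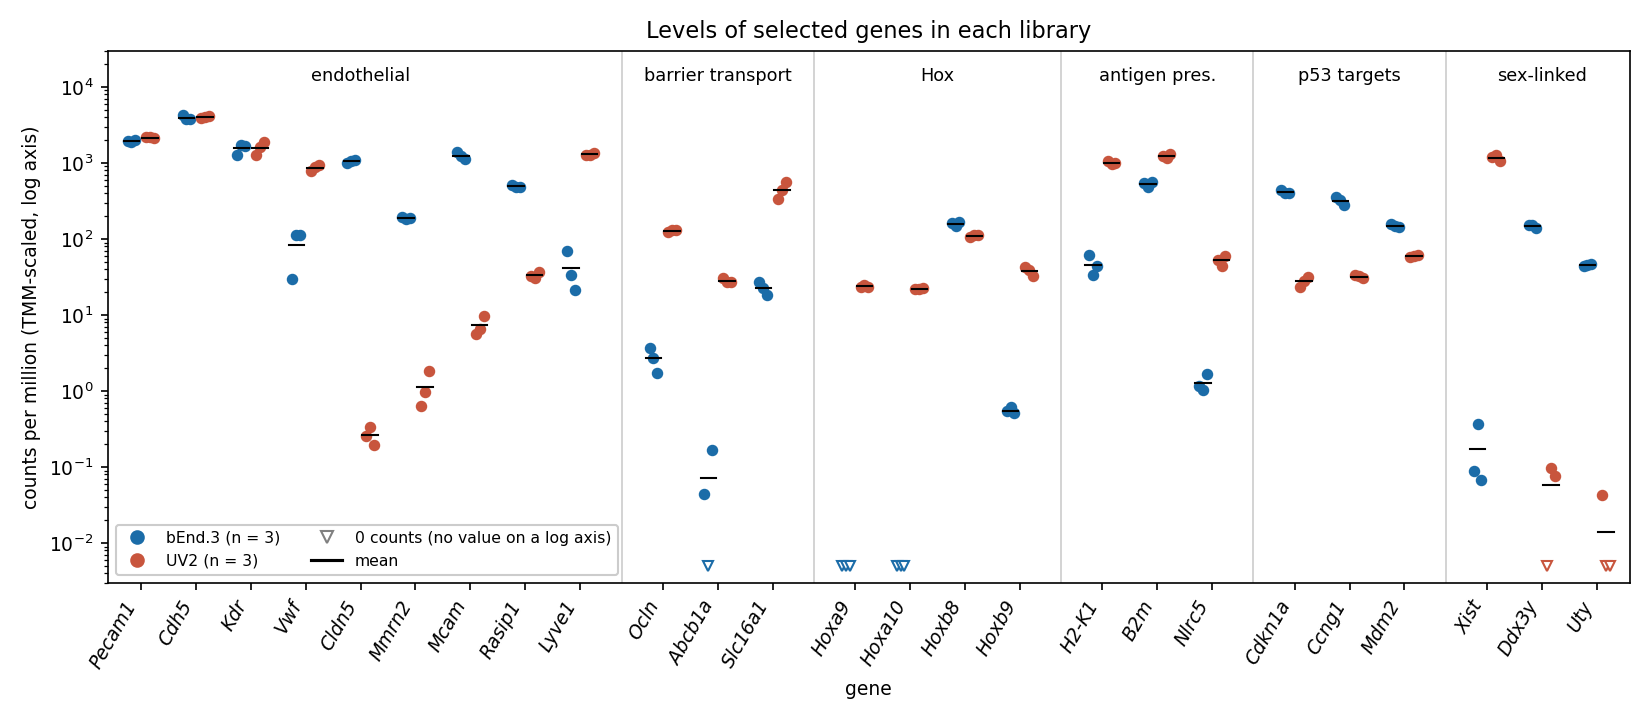
Each point is the CPM of a gene after TMM scaling (log axis) in a library of bEnd.3 (blue) or UV2 (red), n = 3 each; short black lines are means, and open triangles at the bottom mark libraries with 0 counts, which a log axis cannot place. Pecam1, Cdh5 and Kdr lie at like levels in both lines, Cldn5 lies near 1052 in bEnd.3 and 0.262 in UV2, and Hoxa9 and Hoxa10 have counts in UV2 alone.

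In the blood-brain barrier list Cldn5 was lower in UV2, and transporters such as Abcb1a and Slc16a1 were higher. Abcb1a, which encodes the efflux pump P-glycoprotein (chromosome 5, 8567091 to 8748575), had 0.0715 ± 0.08795 CPM in bEnd.3 and 28.3 ± 2.198 CPM in UV2 (log2 fold change 8.41, SE 0.35, adjusted p = 8.71e-07). With only 6 counts behind the bEnd.3 value, its log2 fold change was 10.05 without bEnd.3 replicate 3. The tight-junction gene Ocln rose from 2.697 ± 0.951 CPM to 129 ± 4.75 CPM (log2 fold change 5.61, SE 0.21), and the monocarboxylate transporter Slc16a1 rose from 22.7 ± 4.36 CPM to 443 ± 109 CPM (log2 fold change 4.29, SE 0.22). In all, 12 of 21 tested members were higher in UV2, 5 were lower and 4 did not pass the test. The counts adjusted over the list alone were the same, and the list was not called against other genes (camera adjusted p = 0.444). Fry, which tests whether a list moves on balance in one direction, called it higher (adjusted p = 0.00472). The 5 lower genes were Cldn5, Cgnl1, Itm2a, Fzd4 and Spock2, and the Cgnl1 call was lost with chromosome medians removed (adjusted p = 0.17).

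Arterial, venous and lymphatic lists each held large changes in both directions, and camera called none of them. The Notch target Hey1 had 0.752 ± 0.331 CPM in bEnd.3 and 41.3 ± 16.03 CPM in UV2 (log2 fold change 5.81, SE 0.44, adjusted p = 1.76e-05), and the arterial ephrin Efnb2 rose from 119 ± 10.3 CPM to 550.2 ± 136 CPM (log2 fold change 2.21, SE 0.18). Gja5, the arterial connexin 40, had 22.00 ± 14.9 CPM in bEnd.3 and 0.0547 ± 0.0581 CPM in UV2 (log2 fold change -8.47, SE 0.89, adjusted p = 8.74e-05). Its log2 fold change was -7.797 without bEnd.3 replicate 2 and -9.63 without UV2 replicate 3. Of the arterial genes, 8 of 19 tested members were higher in UV2, 6 were lower and 5 did not pass the test, and adjusted over the list alone 9 were higher and 6 lower. The median of the list was 0.53, while its mean was -0.84 and camera gave the direction down (adjusted p = 0.531). Of the venous genes, 4 of 10 tested members were higher in UV2, 4 were lower and 2 did not pass the test, or 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.961). Vcam1, the leukocyte adhesion molecule, rose from 14.97 ± 3.200 CPM to 99.3 ± 12.4 CPM (log2 fold change 2.74, SE 0.17, adjusted p = 5.71e-06), as did Nrp2, Sele and Lrg1, whose log2 fold change of 1.76 was 0.98 without UV2 replicate 3. Aplnr, the apelin receptor, fell from 129.7 ± 75.03 CPM to 3.65 ± 3.35 CPM (log2 fold change -5.11, SE 0.66, adjusted p = 0.000275), and its log2 fold change was -6.21 without UV2 replicate 3. Selp, Bgn and Tmem252 were the other lower venous genes, and the log2 fold change of Bgn, -3.16, was -4.46 without UV2 replicate 1. The lymphatic hyaluronan receptor gene Lyve1 rose from 41.3 ± 24.97 CPM to 1311 ± 49.8 CPM (log2 fold change 4.99, SE 0.42, and 5.59 without bEnd.3 replicate 1). Podoplanin, Pdpn, had 0 counts in bEnd.3 and 5.98 ± 1.71 CPM in UV2, at least 152-fold higher (adjusted p = 5.53e-05). Prox1, the regulator of lymphatic identity, held 1 count in bEnd.3 and 0 in UV2 and was not tested. Among lymphatic genes 6 of 11 tested members were higher in UV2, 2 were lower and 3 did not pass the test. The counts adjusted over the list alone were the same, and the camera adjusted p was 0.259, while fry called the list higher (adjusted p = 0.000784). Itga9 (log2 fold change -2.61, SE 0.34, adjusted p = 0.000289) and Stab2 were the 2 lower ones.

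Tip cell genes, which mark sprouting endothelium, were lower in UV2 on balance. Mcam, an endothelial adhesion molecule (chromosome 9, 44134658 to 44142727), fell from 1244 ± 133 CPM to 7.31 ± 2.15 CPM (log2 fold change -7.403, SE 0.23, adjusted p = 2.11e-07), and Igfbp3 fell from 1811 ± 425 CPM to 154 ± 58.2 CPM (log2 fold change -3.56, SE 0.33). In the list 3 of 19 tested members were higher in UV2, 11 were lower and 5 did not pass the test. These counts were the same when adjusted over the list alone. The 3 higher genes were Angpt2, Flt4 and Vegfc. Angpt2, the Tie2 ligand, rose from 6.23 ± 4.99 CPM to 113 ± 13.5 CPM (log2 fold change 4.21, SE 0.46, adjusted p = 0.000113), a log2 fold change of 5.07 without bEnd.3 replicate 1. Camera called the list lower (adjusted p = 0.0335; adjusted p = 0.505 with an estimated correlation), and it was not called without bEnd.3 replicate 1 (adjusted p = 0.101). Secreted growth and angiocrine factors went both ways, and 13 of 34 tested members were higher in UV2, 12 were lower and 9 did not pass the test. Adjusted over the list alone the counts were the same, with a camera adjusted p of 0.531, and fry called the list lower (0.0261). Gas6 fell from 78.2 ± 30.1 CPM to 0.123 ± 0.0722 CPM (log2 fold change -9.201, SE 0.53), and the neurotrophin Bdnf rose from 2.35 ± 0.8004 CPM to 28.5 ± 2.75 CPM (log2 fold change 3.62, SE 0.22).

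Genes of leukocyte adhesion and inflammation were higher in UV2. The chemokine Cx3cl1 rose from 2.16 ± 0.395 CPM to 108 ± 10.1 CPM (log2 fold change 5.62, SE 0.14), Ccl2 rose from 94.4 ± 54.6 CPM to 452 ± 61.6 CPM (log2 fold change 2.26, SE 0.37), and Cxcl5 had 0 counts in bEnd.3 and 2.64 ± 1.13 CPM in UV2, at least 67.2-fold higher. In this list 17 of 23 tested members were higher in UV2, 2 were lower and 4 did not pass the test. Counts adjusted over the list alone were the same. Ptgs2, the inducible cyclooxygenase, had 21.7 ± 13.1 CPM in bEnd.3 and 0.202 ± 0.0903 CPM in UV2 (log2 fold change -6.72, SE 0.61, adjusted p = 4.47e-05, and -6.11 without bEnd.3 replicate 1), and with P-selectin, Selp, it made up the 2 lower genes. The list was called higher (camera adjusted p = 0.000815; adjusted p = 0.505 with an estimated correlation). Its median log2 fold change was 2.08.

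Antigen presentation genes of the MHC class I pathway were higher in UV2. The class I heavy chain H2-K1 rose from 46.2 ± 13.9 CPM to 1012 ± 45.1 CPM (log2 fold change 4.45, SE 0.21), H2-D1 from 536 ± 48.5 CPM to 2035 ± 72.97 CPM (log2 fold change 1.93, SE 0.09), and the light chain B2m from 529.9 ± 37.6 CPM to 1229 ± 73.2 CPM (log2 fold change 1.21, SE 0.08). Nlrc5, a transactivator of class I genes (chromosome 8, 94434335 to 94527272), rose from 1.28 ± 0.338 CPM to 52.8 ± 7.97 CPM (log2 fold change 5.34, SE 0.20, adjusted p = 5.14e-07). Of the list, 13 of 16 tested members were higher in UV2, 2 were lower and 1 did not pass the test. These counts were the same when adjusted over the list alone. The 2 lower genes were the immunoproteasome subunits Psmb8 (log2 fold change -0.596, SE 0.10, adjusted p = 0.00108) and Psmb10 (log2 fold change -0.38, SE 0.08), and the transporter subunit Tap2 did not pass (log2 fold change 0.03, SE 0.09, adjusted p = 0.796). Camera called the list higher (adjusted p = 9.77e-05; adjusted p = 0.415 with an estimated correlation). H2 heavy chains are near-identical copies that differ between strains, so reads may have been shared among them or lost against the C57BL/6 reference, and their values are uncertain.

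Interferon-stimulated genes went both ways. Of these, 11 of 30 tested members were higher in UV2, 12 were lower and 7 did not pass the test. Counts adjusted over the list alone were the same. Cxcl10 rose from 1.53 ± 0.621 CPM to 10.3 ± 1.03 CPM (log2 fold change 2.75, SE 0.28, adjusted p = 7.98e-05), while the antiviral Oas2 fell from 19.7 ± 11.7 CPM to 0.924 ± 0.411 CPM (log2 fold change -4.39, SE 0.63, adjusted p = 0.00049) and Ifit2 from 148 ± 5.299 CPM to 22.5 ± 6.73 CPM. The median was 0.07, the mean -0.14 and the camera direction down (adjusted p = 0.752). Oas, Ifit and H2 genes belong to families of close copies, among which the counting could have split reads.

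Most markers of other cell types had too few counts to test, and some of those tested were higher in UV2, as the inflammatory and antigen presentation lists were. Among haematopoietic markers, lysozyme Lyz2 rose from 1.27 ± 0.392 CPM to 330.3 ± 55.3 CPM (log2 fold change 8.05, SE 0.24, adjusted p = 1.80e-07), the tetraspanin Cd53 from 0.172 ± 0.0511 CPM to 28.6 ± 2.58 CPM (log2 fold change 7.35, SE 0.19, adjusted p = 1.18e-07) and the lysosomal Cd68 from 116 ± 37.2 CPM to 285 ± 49.8 CPM. The fourth tested marker, Csf1r, stood at 0.477 ± 0.222 against 0.561 ± 0.229 CPM (log2 fold change 0.23, SE 0.46), with bEnd.3 first. The pan-leukocyte Ptprc held 1 count in bEnd.3 and 0 in UV2, Adgre1 and C1qa held 0 in both, and Tyrobp held 0 and 1. The tested haematopoietic markers were 3 higher and 1 not past the test, with the same counts adjusted over the list alone. They were called higher (camera adjusted p = 0.00012; adjusted p = 0.0822 with an estimated correlation). All 3 tested fibroblast markers, Pdgfra (log2 fold change 2.39, SE 0.34, adjusted p = 0.000453), Col3a1 and Pi16, were higher, at 10.99 ± 4.52 CPM for Pdgfra, 32.1 ± 16.6 CPM for Col3a1 and 0.729 ± 0.171 CPM for Pi16 in UV2, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.28) except with the replicate number as a block (adjusted p = 0.0461) and by fry (0.00371). Of 2 tested mural cell markers, Pdgfrb rose from 0.287 ± 0.131 CPM to 4.36 ± 1.27 CPM (log2 fold change 3.94, SE 0.40, adjusted p = 7.35e-05) and Anpep did not pass (log2 fold change -0.46, SE 0.39) except without bEnd.3 replicate 1 (adjusted p = 0.025), adjusted over the list alone as well (camera adjusted p = 0.531, while fry called the list higher at 0.00864). Of 2 tested neural markers, 1 was higher and 1 lower, and Tubb3 rose from 0.0525 ± 0.0468 CPM to 3.21 ± 0.378 CPM (log2 fold change 5.81, SE 0.45, adjusted p = 1.75e-05), also adjusted over the list alone (camera adjusted p = 0.488, with a fry call higher at 0.0022). Grhl2, the only epithelial marker with enough counts, stood at 0.698 ± 0.186 against 0.695 ± 0.167 CPM (log2 fold change -0.01, SE 0.32, adjusted p = 0.973, not past the test over the list alone either), and no mesothelial marker was tested.

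Mesenchymal and matrix genes split. The gelatinase Mmp2 rose from 4.38 ± 0.512 CPM to 111 ± 7.12 CPM (log2 fold change 4.66, SE 0.11, adjusted p = 7.56e-08). N-cadherin, Cdh2 (chromosome 18, 16588877 to 16809246), stood at 20.5 ± 1.88 CPM in bEnd.3 and held 3 counts in UV2, all in replicate 3, a ratio of 475 (95% counting interval 162 to 2305) (fitted log2 fold change -11.94 without that library), and vimentin, Vim, fell from 8529.5 ± 689 CPM to 3264 ± 186 CPM (log2 fold change -1.39, SE 0.10). In the mesenchymal list 6 of 18 tested members were higher in UV2, 7 were lower and 5 did not pass the test. These counts were the same when adjusted over the list alone. Its median of -0.19 and mean of -0.08 were negative while the camera direction was up (adjusted p = 0.961). Of fibrillar collagen and matrix genes, 4 of 17 tested members were higher in UV2, 9 were lower and 4 did not pass the test, as adjusted over the list alone. Elastin, Eln, fell from 72.2 ± 41.7 CPM to 0.511 ± 0.0277 CPM (log2 fold change -7.13, SE 0.69), and Col6a2 fell from 1.25 ± 0.624 CPM to 0 counts, at least 29.3-fold lower (adjusted p = 0.00154). The 4 higher ones were Col3a1, Col12a1, Thbs1 and Vcan, of which the collagen III gene Col3a1 had 0.954 ± 0.672 CPM in bEnd.3 and 32.1 ± 16.6 CPM in UV2 (log2 fold change 5.13, SE 0.57, adjusted p = 0.000123, and 5.73 without bEnd.3 replicate 1). For Vcan the log2 fold change was 4.47, and 5.096 without bEnd.3 replicate 2. This matrix list was not called (camera adjusted p = 0.297) except without bEnd.3 replicate 1, where it was lower (adjusted p = 0.0266), and by fry (0.0129, also lower). Of basement membrane genes, 8 of 17 tested members were higher in UV2, 4 were lower and 5 did not pass the test. The counts adjusted over the list alone were the same, and the camera adjusted p was 0.531, while fry called the list higher (0.0113). Lower were Col4a1, Col4a2, Lama3 and Nid2, the last with log2 fold change -6.19, SE 0.46, adjusted p = 1.48e-05. Col18a1 rose from 807 ± 39.98 CPM to 2682 ± 141 CPM, and the laminin Lamb3 held 1 count in bEnd.3 and 1.84 ± 0.247 CPM in UV2, a ratio of 141 (95% counting interval 24.9 to 5622) (fitted log2 fold change 8.496 without bEnd.3 replicate 2). Of TGF-beta and BMP response genes, 6 of 12 tested members were higher in UV2, 5 were lower and 1 did not pass the test. Adjusted over the list alone the counts were the same, with a camera adjusted p of 0.752, and fry called the list higher (0.00955). Ltbp2, a matrix protein, had 0.145 ± 0.0943 CPM in bEnd.3 and 109 ± 60.8 CPM in UV2 (log2 fold change 9.51, SE 0.68, adjusted p = 1.22e-05). Id3 rose from 4.22 ± 0.757 CPM to 59.5 ± 4.802 CPM. The lower ones were Pmepa1 (log2 fold change -4.73, SE 0.15, adjusted p = 2.17e-07), Id1, Id2, Skil and Bambi, whose call was lost with chromosome medians removed (adjusted p = 0.12) and without bEnd.3 replicate 3 (0.0929), UV2 replicate 1 (0.084), UV2 replicate 2 (0.106) or UV2 replicate 3 (0.0622).

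Hox genes, which encode positional identity factors, were higher in UV2, among them genes of the HOXA cluster. Hoxa9 (chromosome 6, 52223097 to 52227370) and Hoxa10 (chromosome 6, 52231197 to 52240854) had 0 counts in bEnd.3 and 24.00 ± 1.03 CPM and 22.3 ± 0.233 CPM in UV2, at least 610.5-fold and at least 566-fold higher. Hoxa5 rose from 0.06697 ± 0.0481 CPM to 10.4 ± 0.302 CPM (log2 fold change 7.202, SE 0.28, and 7.901 without bEnd.3 replicate 2). The flanking genes of the cluster, Skap2 and Hibadh, were expressed in both lines, at 84.2 ± 7.75 against 58.2 ± 6.26 CPM and 50.2 ± 2.51 against 64.97 ± 1.04 CPM, with bEnd.3 first. In the HOXB and HOXD clusters both lines had transcripts, and Hoxb9 rose from 0.553 ± 0.0522 CPM to 38.5 ± 4.89 CPM (log2 fold change 6.11, SE 0.17) and Hoxd10 from 3.73 ± 0.926 CPM to 67.9 ± 1.803 CPM (log2 fold change 4.198, SE 0.17). Over all clusters 18 of 22 tested members were higher in UV2, 2 were lower and 2 did not pass the test. Counts adjusted over the list alone were the same. The 2 lower genes were Hoxb7 (log2 fold change -0.37, SE 0.06) and Hoxb8 (log2 fold change -0.53, SE 0.07, adjusted p = 0.000262), and Hoxd4 (log2 fold change -0.28, SE 0.14, adjusted p = 0.11) and Hoxd8 (log2 fold change 0.09, SE 0.09, adjusted p = 0.371) did not pass. Hoxd4 passed without bEnd.3 replicate 1 (adjusted p = 0.03), and Hoxd8 with chromosome medians removed (adjusted p = 0.00795). The median log2 fold change was 4.95, or 3.96 with genes at 0 counts placed at their bound. Camera called the list higher (adjusted p = 2.79e-11; adjusted p = 0.0438 with an estimated correlation).

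Of 15 listed genes downstream of Wnt/beta-catenin signalling, 9 had too few counts to test, and 4 of the 6 tested were lower in UV2. Sox17, an endothelial transcription factor (chromosome 1, 4490928 to 4497426), fell from 59.9 ± 6.51 CPM to 0.324 ± 0.0911 CPM (log2 fold change -7.49, SE 0.18, adjusted p = 8.90e-08), and Dkk2, a secreted Wnt modulator, fell from 178 ± 34.4 CPM to 3.59 ± 0.212 CPM (log2 fold change -5.63, SE 0.18, adjusted p = 2.25e-07). Ccnd1, cyclin D1, fell from 731 ± 208 CPM to 79.4 ± 33.5 CPM (log2 fold change -3.204, SE 0.35), and the ubiquitin ligase Znrf3 fell from 7.67 ± 0.709 CPM to 4.41 ± 0.882 CPM. Apcdd1 (log2 fold change -0.395, SE 0.27, adjusted p = 0.232) and Sp5 (log2 fold change -0.11, SE 0.45, adjusted p = 0.839) did not pass, apart from Apcdd1 without UV2 replicate 1 (adjusted p = 0.00362). The counts of 0 higher, 4 lower and 2 not past were the same adjusted over the list alone, and the list was called lower (camera adjusted p = 0.000152; adjusted p = 0.0822 with an estimated correlation). Sox17, Dkk2 and Ccnd1 have regulators besides Wnt, and the commonly used target Axin2 held only 11 counts in bEnd.3 and 32 in UV2.

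Cell cycle genes were lower in UV2. Ccne1, cyclin E1, fell from 14.2 ± 1.44 CPM to 3.38 ± 1.46 CPM (log2 fold change -2.08, SE 0.30, adjusted p = 0.000506), and Tyms, which makes thymidylate, fell from 69.8 ± 5.89 CPM to 16.98 ± 2.81 CPM (log2 fold change -2.04, SE 0.13). The proliferation marker Mki67 fell from 231 ± 19.96 CPM to 74.4 ± 41.9 CPM (log2 fold change -1.64, SE 0.42, adjusted p = 0.00915), with 87.9, 108 and 27.3 CPM in UV2 replicates 1, 2 and 3. In this list 1 of 30 tested members were higher in UV2, 25 were lower and 4 did not pass the test. These counts were the same when adjusted over the list alone. The replication licensing gene Mcm2 was the higher one, at 99.5 ± 12.8 against 142 ± 6.55 CPM (log2 fold change 0.51, SE 0.10, adjusted p = 0.00219). Ccnb1 (log2 fold change -0.51, SE 0.42), Kif11 (log2 fold change -0.88, SE 0.38), Mcm4 (log2 fold change -0.01, SE 0.11) and Mcm6 (log2 fold change 0.03, SE 0.10) did not pass. Kif11 passed in limma-voom (adjusted p = 0.0368), with the replicate number as a block (0.0286) and without UV2 replicate 3 (0.00319), and Mcm6 passed with chromosome medians removed (0.0245). The list was called lower (camera adjusted p = 0.00698; adjusted p = 0.772 with an estimated correlation).

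Most genes of the list of p53 targets were lower in UV2. Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090979 to 29100722), fell from 413 ± 21.9 CPM to 27.8 ± 4.16 CPM (log2 fold change -3.89, SE 0.12, adjusted p = 2.25e-07), and Ccng1 (chromosome 11, 40748552 to 40755309) fell from 321 ± 37.96 CPM to 32.04 ± 1.35 CPM (log2 fold change -3.33, SE 0.10, adjusted p = 2.26e-07). Zmat3 fell from 229 ± 7.29 CPM to 44.1 ± 1.34 CPM, the p53 ubiquitin ligase Mdm2 from 151 ± 7.21 CPM to 59.96 ± 1.37 CPM, and the pro-apoptotic Bax from 198 ± 8.86 CPM to 64.3 ± 1.11 CPM. Of 14 tested members 0 were higher and 13 lower, as adjusted over the list alone, and Fas alone did not pass (log2 fold change -0.38, SE 0.26, adjusted p = 0.233), except without bEnd.3 replicate 1 (adjusted p = 0.0284). Camera called the list lower (adjusted p = 8.65e-10; adjusted p = 0.0438 with an estimated correlation), with a median log2 fold change of -1.37.

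Camera called neither metabolic list, although single enzymes differed widely. The hexokinase Hk2 rose from 0.976 ± 0.532 CPM to 45.9 ± 4.52 CPM (log2 fold change 5.598, SE 0.28) and the stress-response gene Ndrg1 from 33.8 ± 7.91 CPM to 886 ± 48.1 CPM (log2 fold change 4.71, SE 0.17), while Egln3, an oxygen-sensing prolyl hydroxylase, fell from 691 ± 214 CPM to 156 ± 16.3 CPM (log2 fold change -2.15, SE 0.23, adjusted p = 0.000101). Of hypoxia and glycolysis genes, 10 of 20 tested members were higher in UV2, 4 were lower and 6 did not pass the test, or 10 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.408), and fry called the list higher (adjusted p = 0.0139). Lower were Egln3, Ldha, Pdk1 and Bnip3, and the carbonic anhydrase Car9 had 1 count in bEnd.3 and 1.04 ± 0.134 CPM in UV2, a ratio of 79.3 (95% counting interval 13.8 to 3176) (fitted log2 fold change 7.695 without bEnd.3 replicate 1). Of cholesterol synthesis genes, 11 of 20 tested members were higher in UV2, 2 were lower and 7 did not pass the test. The counts adjusted over the list alone were the same, and the camera adjusted p was 0.469. Hsd17b7 rose from 13.98 ± 4.45 CPM to 67.3 ± 9.896 CPM (log2 fold change 2.27, SE 0.23, adjusted p = 8.36e-05). The 2 lower genes were Insig1 (log2 fold change -0.78, SE 0.16, adjusted p = 0.00309) and Stard4.

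**Figure D2:**
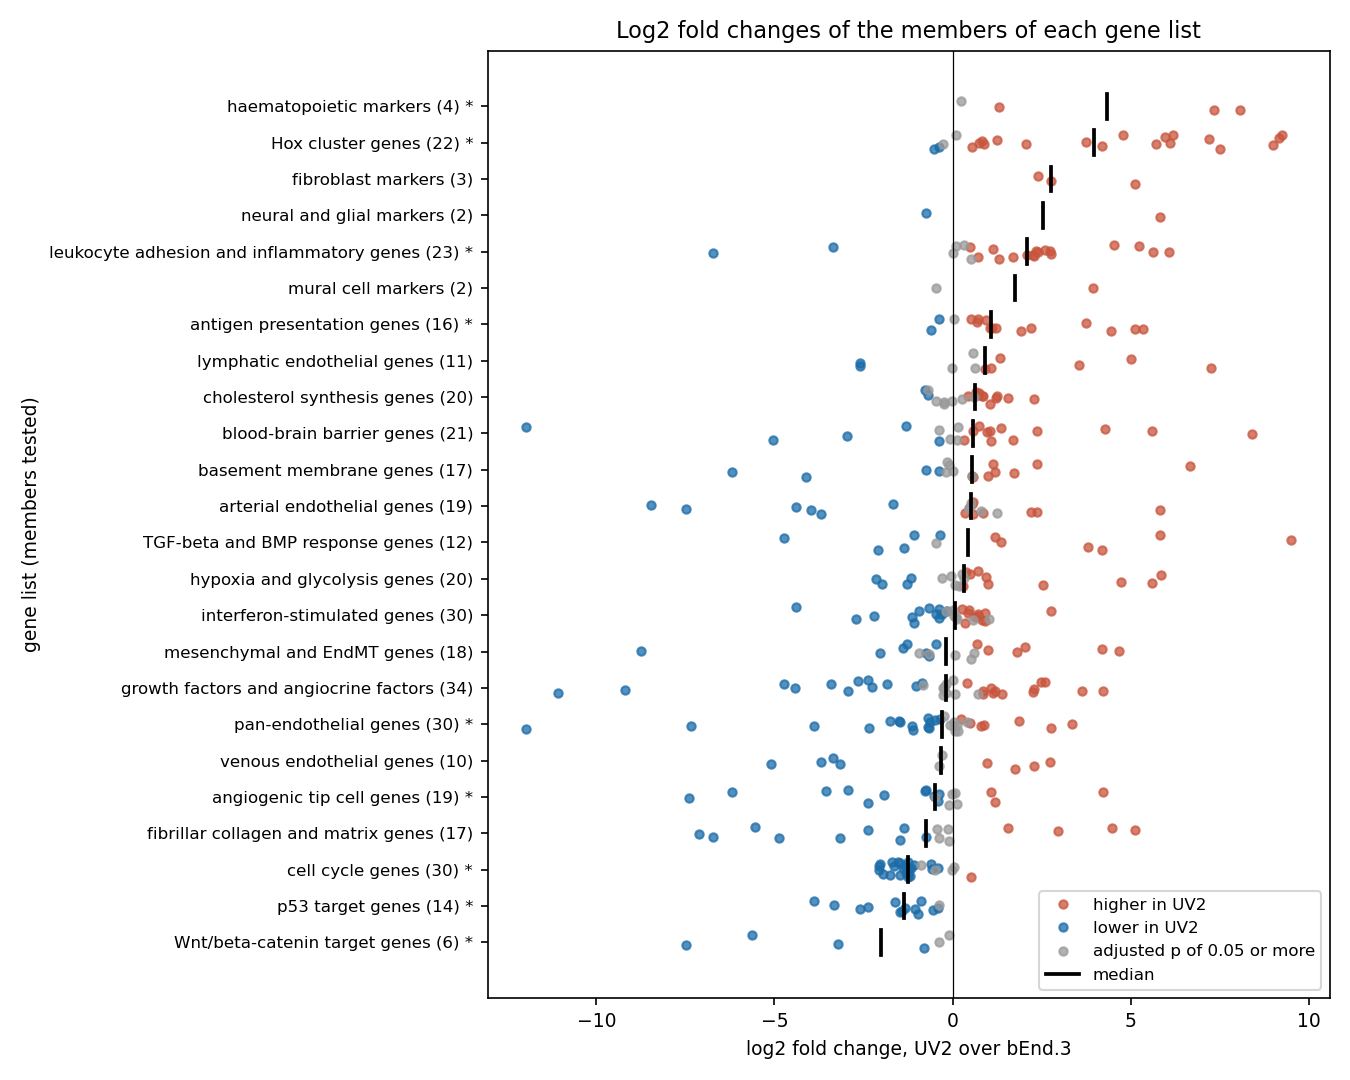
Each point is the log2 fold change (UV2 over bEnd.3) of a tested member of the list named on the vertical axis, red where higher in UV2, blue where lower and grey where the adjusted p was 0.05 or more; genes with 0 counts in a line stand at their bound, black bars are medians, and a star marks lists called by camera with the preset correlation. The p53 target genes lie left of 0 with a median of -1.37, and most Hox cluster genes lie right of 0, with a median of 3.96 at the bounds.

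Whole chromosomes were shifted against each other, a pattern looked for after the data were examined. Over 9576 genes with edgeR's average log2 CPM above 3, the median log2 fold change was 0.72 on chromosome 14, 0.53 on 13 and 0.48 on 15. Chromosome 4 was parted at the single point that best separated these same fold changes, and so its parts were not tested. Genes from there on (position 126753547) had a median of 0.70 over 216 genes, and those before it a median of 0.04 over 349. The lowest medians were -0.29 on chromosome 1, -0.27 on 2, -0.26 on 9 and -0.25 on 7. Each UV2 library set against the bEnd.3 mean gave medians from 0.68 to 0.74 for chromosome 14 and from 0.68 to 0.70 for the distal part of 4. Over whole chromosomes, camera called 14 (adjusted p = 5.46e-12), 13 (2.62e-07), 15 (3.21e-06), 4 (0.00547) and 3 (0.0402) higher in UV2, and 1 (0.00207), 2 (0.00107), 7 (0.00375) and 9 (0.00237) lower. With an estimated correlation the calls of 14 (adjusted p = 0.0429), 15 (0.00767), 4 (0.0429), 2 (0.0122) and 9 (0.0114) stayed, and those of 13 (0.126), 3 (0.242), 1 (0.0732) and 7 (0.0732) were lost.

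**Figure D3:**
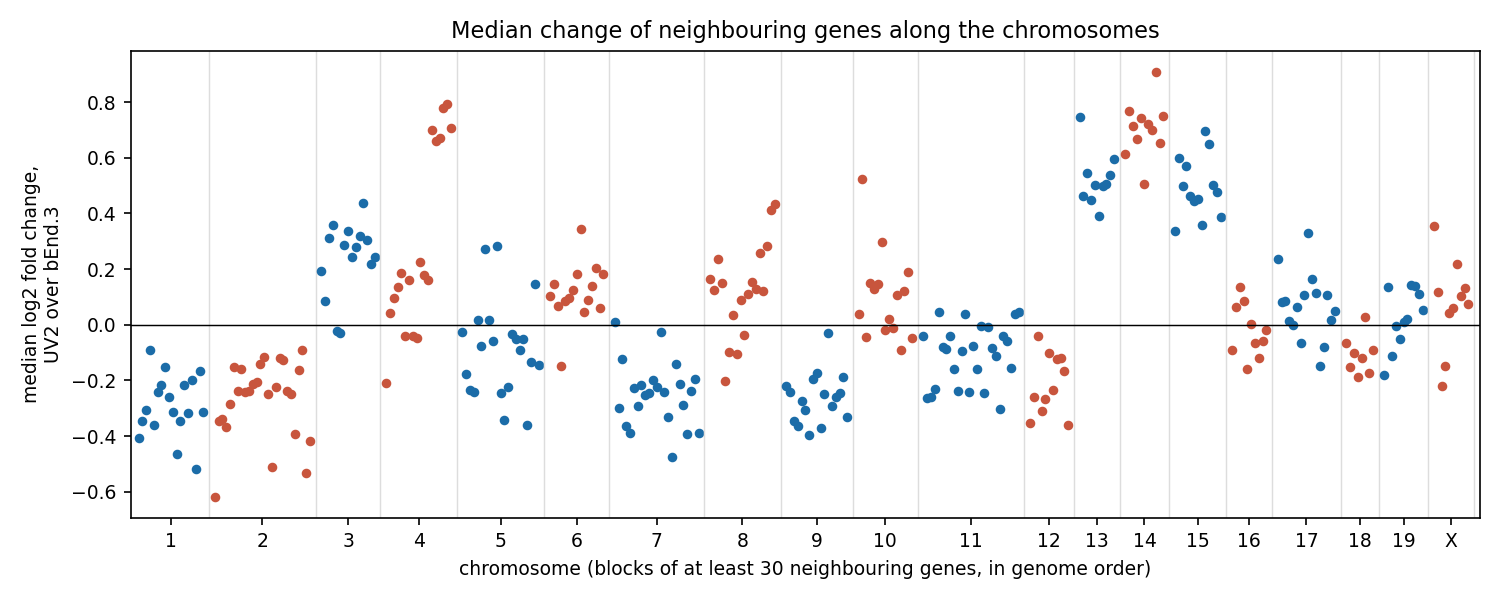
Each point is the median log2 fold change (UV2 over bEnd.3) of a block of at least 30 neighbouring genes in genome order, with colours alternating between chromosomes only to part them. Blocks of chromosomes 13, 14 and 15 and of the distal part of 4 lie above 0.3, and those of chromosomes 1, 2, 7 and 9 lie mostly below 0.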

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

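The setting with chromosome medians removed was chosen only after the data were seen. The 196 results were 166 single genes, 24 set tests and 6 counts. Over these and 16 settings, 2643 of 2737 alternative values were kept. For genes and set tests this means the same direction and side of the threshold, and for counts a change within 1.5 times. The single genes were named mainly for large changes or after their values were seen, so this share does not carry over to all called genes. Too few counts kept 9 of 15 Wnt targets from being tested, and whether depth or lack of expression set this was not tested. The pseudocount alternative gave no value because the table holds counts. Where a value moved below, the cause was not tested.

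Leaving out each library in turn gave 3998 to 4416 genes higher, 3765 to 4326 lower, 1286 to 1454 higher and 983 to 1192 lower by more than 2-fold, 8 to 8 called gene lists and 1 to 1 marker lists. The counts of genes higher in UV2 and genes lower in UV2 were 4465 and 4232 with DESeq2 and 4346 and 4240 with limma-voom. They were 3918 and 4716 with total counts, and 3811 and 3965 with chromosome medians removed. Of the 8538 genes called as reported, 8199 were also called with DESeq2, 8484 with limma-voom and 8150 with total counts. With chromosome medians removed only 6816 of them were called, among 7776 calls. With an estimated correlation, 2 gene lists and 0 marker lists were called, and fry, which does not compare a list with other genes, called 15 and 4.

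Whether the numbers in the titles pair the libraries stays open. Over all tested genes, deviations of same-numbered libraries from the mean of their line correlated at 0.085, 0.161 and 0.2001. Over 9303 genes with a mean log2 CPM above 3 they correlated at 0.164, 0.322 and 0.3397. In both sets each library correlated best with its own number, a hint from the data and not the design. With the replicate block, genes higher in UV2 numbered 4380 and genes lower in UV2 4302. It called 8 gene lists and 2 marker lists, the added one being the fibroblast markers (adjusted p = 0.0461), and Kif11 passed (adjusted p = 0.0286).

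Directions that turned were of results not past the threshold as reported, except Rrm2b. The venous list turned with fry (adjusted p = 0.566), total counts (0.984), no filter (0.929), chromosome medians removed (0.814), and without bEnd.3 replicate 3 (0.97) or UV2 replicate 2 (0.971). The mesenchymal list turned with the CPM filter (0.998) and, with the arterial list, without UV2 replicate 1 (0.867 and 0.711). Log2 fold changes with total counts were -0.0361 for Cdh5, -0.0279 for Kdr, -0.037 for Tap2 and -0.0373 for Mcm6. With chromosome medians removed they were -0.109 for Cdh5, -0.0441 for Tap2, 0.156 for Sp5, 0.00703 for Mcm4 and -0.234 for Rrm2b. Over the fits that left out 1 library each, the log2 fold changes ran from -0.0007027 to 0.08624 for Cdh5, -0.0942 to 0.1868 for Kdr, -0.01929 to 0.1305 for Tap2 and -0.1166 to 0.6793 for Csf1r. They ran from -0.4046 to 0.2866 for Sp5, -0.08041 to 0.08836 for Mcm4, -0.0476 to 0.1001 for Mcm6 and -0.2132 to 0.1539 for Grhl2. The adjusted p of the arterial list ran from 0.3967 to 0.711, that of the mesenchymal list from 0.7603 to 0.9556 and that of the venous list from 0.711 to 0.9714.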

Other observations

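The tests of the gene families in the next 2 paragraphs, of the chromosomes, of antigen presentation and of genes at the floor were chosen only after the results were seen, while the second p53 list and the splits of the libraries were set before. D-type cyclins, which drive entry into the cell cycle, were lower in UV2 in all 3 members. Ccnd2 fell from 197 ± 32.7 CPM to 0.331 ± 0.216 CPM (log2 fold change -9.21, SE 0.29, adjusted p = 2.33e-07) and Ccnd3 from 144 ± 6.48 CPM to 74.8 ± 2.47 CPM (log2 fold change -0.94, SE 0.06), next to Ccnd1 (camera p = 2.30e-05, and 0.0129 with an estimated correlation). Of 20 claudin genes only 4 were tested, Cldn5 among them. Cldn15 rose from 2.59 ± 0.2700 CPM to 29.97 ± 7.94 CPM and Cldn12 from 16.6 ± 1.37 CPM to 36.7 ± 4.39 CPM, and Cldn1 stood at 0.515 and 0.991 CPM without passing. The claudin median was positive, at 1.05, while the camera direction was down (p = 0.042, and p = 0.108 with an estimated correlation).

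Schlafen genes split, with 2 of 7 tested members higher and 5 lower. Camera gave a p of 0.159 for the family. The lower call of Slfn8 was lost in DESeq2 (adjusted p = 0.0845), in limma-voom (0.0603) and with no filter on low counts (0.0597). It was also lost with the CPM filter (0.051), with chromosome medians removed (0.118) and without any single library (up to 0.13) except bEnd.3 replicate 3. Slfn4 rose from 0.836 ± 0.0675 CPM to 1102 ± 184 CPM (log2 fold change 10.35, SE 0.19), while Slfn3 fell from 145 ± 3.06 CPM to 14.8 ± 1.96 CPM (log2 fold change -3.303, SE 0.10), and these neighbouring close copies are uncertain where reads fit several of them. Of 13 tested Eph receptors and ephrins, 7 were higher and 4 lower. Camera gave a p of 0.224 for them. Ephb1 stood at 87.8 ± 19.9 CPM in bEnd.3 with 1 count in UV2, a ratio of 6264 (95% counting interval 1124 to 247451) and a fitted log2 fold change of -14.05 without UV2 replicate 3. Ephb2 had 0 counts in bEnd.3 and 15.3 ± 2.37 CPM in UV2, at least 388-fold higher, and Epha4 rose from 8.76 ± 0.922 CPM to 89.1 ± 9.53 CPM. Of 14 scavenger receptors and lysosomal proteases, 7 were higher and 5 lower, the lower ones being Stab2, Scarb1, Ctsd, Ctsh and Ctsz. Camera gave a p of 0.349 for this group.

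Genes of chromosomes 13, 14 and 15 and of the distal part of 4 were higher in UV2 together. On 13, 14 and 15, 100% of blocks of 30 neighbouring genes had a median above 0.3, and 84.8% of the genes lay above 0. The shift was thus not limited to a few strongly changed genes. These chromosomes were picked for their high medians in the same data, so the shares describe the shift and do not test its cause. Strain variants against the reference would shift the autosomes alike if they were spread evenly over them, and the chromosome medians spanned 1.00. How the variants are spread over the chromosomes was not examined, so strain variants are not excluded. A difference in copy number of whole chromosomes or segments between the lines is a candidate explanation, found and tested on the same data, and DNA was not analysed here. Regional regulation of expression was not tested.

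Most antigen presentation genes were higher in UV2, with exceptions inside the MHC (Psmb8 lower, Tap2 not past the test) and outside it (Psmb10 lower). Camera no longer called the list with an estimated correlation (adjusted p = 0.415). Of 6 tested members outside the MHC, 5 were higher, against 33.9% of all tested genes, and strain variants in these genes were not tested. All 5 tested H2 genes of the list were higher. For these the haplotype and the line cannot be told apart. BALB/c reads may be lost against the reference, and reads by allele were not analysed here. Outside the list, H2-Q1, H2-Q2 and H2-Q6 held 0, 1 and 2 counts in bEnd.3 and 997, 2837 and 4999 in UV2, where the same limit holds. The line itself stays an open explanation.

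In all, 69 genes were at the floor in 1 line and abundant in the other, 41 in bEnd.3 and 28 in UV2. For those at the floor in UV2, 25 were not Y-linked, which argues against strain variants, since UV2 carries a BALB/c parent's alleles and bEnd.3 reads of BALB/c were mapped at these genes. For the 41 in bEnd.3, loss of BALB/c reads and lack of expression cannot be told apart without reads by allele. Both neighbouring expressed genes were detected at 75.8% of the genes that are not Y-linked (50 of 66). The shares over all expressed genes were 89.1% in bEnd.3 and 91.5% in UV2. The 75.8% lies between the bounds set for and against deletions that reach the neighbours. Genes without both include Hoxa9 and Hoxa10, close together in a cluster, and the family members H2-Q1, H2-Q2 and H2-Q6. Such genes are not independent, and the genes flanking the HOXA cluster, Skap2 and Hibadh, were expressed in both lines. The share thus cannot decide on such deletions, which stay open.

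A second list of p53 targets, sharing no member with the first, was lower in UV2 (camera p = 1.04e-05, and 0.0319 with an estimated correlation). Of 18 tested members 14 were lower, 3 higher (Rrm2b, Apaf1 and Abhd4) and 1 did not pass, with a median log2 fold change of -0.64. The Abhd4 call was lost with chromosome medians removed (adjusted p = 0.752), and that of Rrm2b was lost with total counts (0.057) and without bEnd.3 replicate 2 (0.0539). With chromosome medians removed Rrm2b was lower, at a log2 fold change of -0.234 (adjusted p = 0.0231). Among the lower ones, Ddit4l stood at 24.3 ± 1.21 CPM in bEnd.3 and had 3 counts in UV2, a ratio of 571 (95% counting interval 195 to 2774) and a fitted log2 fold change of -12.19 without UV2 replicate 3.

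The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 with as many genes higher (4306) and lower (4232) and as many beyond 2-fold (1350 and 1120), and the highest of the others gave 0. For called gene lists, 4 of the 10 splits gave as many as the real 8, the highest other being 9. For marker lists 3 of the 10 gave as many as the real 1, the highest other being 2. Each of the other splits held libraries of both lines in both groups. A part of the line difference thus stayed in their contrast, and a part widened the spread within their groups. Their 0 called genes and their called lists therefore do not measure chance alone, and the splits cannot decide on it. The number of called lists with the preset correlation is not taken as support for the real split.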
